A study of Mus musculus and Homo sapiens with 64 samples.

How the data were processed

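RNA sequencing libraries were analysed from K562 cells, a human erythroleukaemia line, and from mouse fetal liver at embryonic day 14.5. The labels name ETO2, the corepressor encoded by Cbfa2t3 in the mouse, as the targeted gene. The first K562 set held 3 libraries labelled Control and 3 labelled KO. The other K562 set, called the rescue set here, held 3 libraries each of wild type (WT), knockout (KO), and knockout cells given back full-length ETO2 (FL) or ETO2 without its TAF110 domain (D1), its HHR domain (D2) or its ZF domain (D4). Total fetal liver gave 6 WT and 6 KO libraries. Cells sorted from fetal liver into 7 gates, named S0_low, S0_med, S1, S2, S3-C, S3-m and S4-S5 in the labels, gave 2 WT and 2 KO libraries per gate. Per the labels' protocols, libraries were made with an Illumina TruSeq mRNA kit from 1 µg of RNA for K562 cells and total liver and from 10 ng for sorted cells. The labels do not say whether replicates were separate cultures, clones or embryos, so the p-values measure only the spread between these samples.

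Each library's deposited file holds raw counts per gene, as whole numbers without normalization, written by featureCounts per the file headers. The headers name featureCounts 1.6.2 with GENCODE release 25 and reverse-stranded counting for the 24 K562 files. They name featureCounts 1.6.0 with release M12 for the 28 files of sorted cells and featureCounts 1.6.4 with release M12 for the 12 files of total liver, both without strand. The submitters' processing notes name HISAT2 2.1.0, Subread, featureCounts 1.6.4, R 3.5.1 and DESeq2 1.22.1, and the builds hg38 and mm10. The command lines in the headers do not ask for reads that map to several places, so the levels of near-identical copies, such as Hba-a1 and Hba-a2, Hbb-bs and Hbb-bt, or the Stfa family, are uncertain. Mouse counts cannot tell a gene from an overlapping antisense gene. Coordinates are those in the count files, on hg38 and mm10. Of 49585 mouse identifiers in the files, 49326 matched a gene symbol. The files do not pair the 57992 human identifiers with names and no name table of human genes was used here, so human genes are given by identifier and the human gene lists were not tested.

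Total counts, in units of M (mega) counts, ran from 16.5 to 43.4 M in the first K562 set, from 11.6 to 24 M in the rescue set and from 4.68 to 21.4 M in total liver. In sorted cells they ran from 0.00992 to 89.8 M. A count of 0 allows a level of up to 3 counts in that library's total, which covers counting error only, since PCR copies are not independent molecules. Counts of replicates were compared by a chi-square ratio over genes with at least 20 counts. The lowest ratio per degree of freedom was 2.37 in the first set, 1.62 in the rescue set, 3.86 in liver and 5.81 in sorted cells, so no pair of replicates came down to sampling noise. D1 3, D2 2 and D4 2 stood apart from their groups, with ratios of 21.6 and 22.2, 64.7 and 40.9, and 18 and 10, against 1.62 to 3.95 for the other pairs of the rescue set.

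Counts were tested with edgeR 4.0.16 in R 4.3.3, with limma 3.58.1 for gene lists and DESeq2 1.42.0 as an alternative. Genes passed filterByExpr with a minimum count of 10, libraries were scaled by TMM factors, and edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was run 2-sided. A gene was called at an adjusted p below 0.05. The first K562 set and total liver had a fit each. The rescue set and the sorted cells each shared 1 fit, so that all groups of a set gave 1 estimate of the spread, and the gates were also compared by a test of the genotype by gate interaction. The fit of the sorted cells treated its libraries as independent, though same-numbered gates may come from the same sample. Expression levels are CPM (counts per M counts of TMM-scaled library size), computed from the deposited counts. These choices, the comparisons, the alternatives and the gene lists were fixed before the data were examined.

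The 24 gene lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the lists of a comparison. They covered embryonic and fetal globins, adult globins, heme synthesis and iron supply, erythroid membrane and cytoskeleton, terminal erythroid maturation, ETO2 partners and corepressors, globin-switching regulators, megakaryocytes and platelets, stem and progenitor cells, granulocytes and monocytes, macrophages, mast cells with basophils and eosinophils, lymphoid cells, hepatoblasts and hepatocytes, endothelial and mesenchymal cells, S phase, G2 and M phase, p53 targets and cell-cycle inhibitors, interferon-stimulated genes, immediate-early and heat shock genes, ribosomal proteins, replication-dependent histones, mitochondrially encoded mRNAs, and sex-linked genes. Lists of genes at least 2-fold higher or lower in the first-set libraries labelled KO were tested in the rescue set with camera and fry. camera compares a list with the other genes, while fry asks only whether its members moved. A first-set score was the mean log2 CPM (prior count 2) of genes at least 2-fold higher in the first-set libraries labelled KO, minus that of genes at least 2-fold lower. It was compared between rescue groups by an exact 2-sided permutation test over the 20 assignments of 3 against 3, whose smallest p is 0.1.

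The genes named were the targeted gene, the globins, and the 10 genes with the largest rise and the 10 with the largest fall (5 and 5 in single gates and for D1, D2 and D4) among called genes with a mean of at least 5 CPM and no overlap between groups. Up to 4 members of each list with the smallest adjusted p were added, with the 10 genes of smallest interaction p and a mean of at least 5 CPM. For human genes at most 2 that rose and 2 that fell were named. Genes named outside this rule are marked as chosen after their values were seen.

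On counts simulated for the real genes with 200 changed genes, 100 per fold, the test on 15512 genes of the first K562 set recovered 88 at 2-fold and 97 at 4-fold with 12 false calls. For KO against WT in the rescue set (16739 genes) it recovered 82 and 86 with 3 false calls, and in total liver (14047 genes) 83 and 98 with 12 false calls. In gates S0_med (14636 genes) and S4-S5 (14556 genes) it recovered 0 at 2-fold and 2 at 4-fold, with 0 false calls in each.

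Replicate numbers were compared between groups through the correlation of same-numbered libraries' deviations across genes. D1 and FL had all 3 correlations above 0.1 (0.12 to 0.38), so their numbers were read as pairing the samples, as a hint from the data only. With the number as a block this comparison gave 10383 genes against 10385 without. Other comparisons of K562 cells and that of total liver did not meet this rule. The rule asked for at least 3 pairs, so the gates of the sort, with 2 libraries per genotype, could not meet it. Their same-numbered libraries correlated at 0.42 in S1, 0.17 in S2 and -0.01 to 0.09 in the other gates, so pairing in the sort was not settled. Alternatives were RLE factors, no low-count filter, a CPM filter, library sizes without globins in the mouse, the replicate block, DESeq2, fits with only the compared groups or the gate's own libraries, limma voom with duplicateCorrelation (consensus correlation 0.03), embryo sex in liver, other forms of the score, and each replicate left out. Alternatives added after seeing the data were sorted cells without the 2 shallowest libraries, the rescue set without D1 3, D2 2 and D4 2, liver without number 1 of both groups, removal of each library's gene length trend in the mouse (a lowess curve of span 0.3), and a block for the first-set lists.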

Results

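The data were gene counts from 64 RNA sequencing libraries. The 6 libraries of the first K562 set held 16.5 to 43.4 M counts (median 28.5) and the 18 of the rescue set 11.6 to 24 M (median 16.8). The 12 total fetal livers held 4.68 to 21.4 M (median 12.2). The 28 libraries of sorted fetal liver cells held a median of 5.78 M and differed widely in depth. KO S0_low 1 held 9918 counts and WT S0_med 1 held 120559, while the others held 0.768 to 89.8 M. Among the libraries next in depth, KO S4-S5 2 held 0.768 M and KO S3-C 1 held 1.09 M.

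The targeted gene was read first in each library. In total liver, Cbfa2t3 (ENSMUSG00000006362, mm10 chromosome 8, 122625141 to 122699109, minus strand), which encodes ETO2, stood at 29.2 ± 3.68 CPM in KO and 34.9 ± 5.5 in WT (SD, n = 6 each). The log2 fold change was -0.25 ± 0.118 (SE) with an adjusted p of 0.092. Without number 1 of both groups it fell by 0.32 (adjusted p = 0.00607), and with the gene length trend of each library removed the log2 fold change was 0.05 (adjusted p = 0.718), which are alternatives chosen after the data were seen. KO livers lay between 26.4 and 36.1 CPM and WT livers between 26.1 and 42.2. In sorted cells Cbfa2t3 passed the test in no gate under edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Its 2 KO libraries stood at 34.2 (from 1 count) and 78.7 CPM in S0_low, against 56.3 and 69.9 in WT. They stood at 49.4 and 68.5 against 75.9 (from 13 counts) and 52.3 in S0_med, at 56.3 and 57.4 against 28.5 and 40.5 in S1, and at 38.2 and 39.9 against 15.5 and 14.7 in S2. In S3-C they stood at 73.4 and 187 against 31.6 and 32.5, in S3-m at 355 and 226 against 32.6 and 81.5, and in S4-S5 at 206 and 77.5 against 23.1 and 84.9. The labels do not say which part of the gene was deleted, so the total count does not check the genotypes, which rest on the labels.

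In K562 cells the targeted gene could not be read by name. The identifier ENSG00000129993 (hg38 chromosome 16, 88874858 to 88977204, minus strand) was picked after the values were seen, as the most abundant of 9 identifiers that were lower in rescue-set KO than WT cells and at least 2-fold above WT in all 4 groups given back ETO2. Its name is not given in the sources used here, so whether it is the targeted gene was not established here. In the rescue set its level was 170 ± 4.16 CPM in WT, 79.1 ± 6.84 in KO, 2210 ± 95 in FL, 579 ± 86.3 in D1, 682 ± 208 in D2 and 1020 ± 89.4 in D4 (SD, n = 3 each). In the first set the libraries labelled Control held 78, 76.1 and 73.4 CPM and those labelled KO held 161, 151 and 161. The first-set difference of 1.05 ± 0.042 (log2, SE; adjusted p = 1.56e-20) thus had the opposite sign to the rescue-set difference of -1.10 ± 0.17 (adjusted p = 3.77e-05). Directions in the first set are therefore given for libraries as labelled.

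The first K562 set asked which genes differ when ETO2 is lost. The libraries labelled KO and Control differed in the levels of many transcripts. ENSG00000179104 (hg38 chromosome 12, 82686880 to 83134870) stood at 14.2 ± 1.03 CPM in libraries labelled KO and 0.118 ± 0.023 in Control (SD, n = 3 each; log2 fold change 6.94, adjusted p = 6.31e-25). ENSG00000115919 stood at 22.5 ± 0.752 and 0.779 ± 0.315 CPM, a log2 difference of 4.80. ENSG00000197956 (chromosome 1, 153534599 to 153536244) had 22.7 ± 0.43 CPM in Control and 0 counts in the libraries labelled KO, which allows up to 0.0974, 0.114 and 0.096 CPM. ENSG00000155974 (chromosome 12, 66347431 to 66804186) likewise had 10.6 ± 0.642 CPM in Control and 0 counts in the libraries labelled KO. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 7916 of 15811 genes differed, of which 3981 were higher and 3935 lower in the libraries labelled KO. At 2-fold or more, 559 were higher and 1054 lower. The libraries of the groups did not overlap for 55.3% of genes, where chance gives 10%.

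The rescue set compared KO with WT cells again in other libraries. In KO cells ENSG00000155974 rose to 14.6 ± 0.37 CPM from 0.0183 ± 0.0316 in WT (SD, n = 3 each; adjusted p = 5.01e-11), the opposite of its direction in the first set as labelled. ENSG00000278530 stood at 10.3 ± 0.763 CPM in KO and had 0 counts in WT, which allows up to 0.177, 0.162 and 0.178 CPM. ENSG00000138650 fell by 8.96 on the log2 scale from 36 ± 0.245 CPM in WT, and ENSG00000075884 fell from 102 ± 1.1 to 0.308 ± 0.167 CPM (adjusted p = 7.7e-15). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 8767 of 17020 genes differed, with 4322 higher and 4445 lower in KO, and 1280 and 2141 of them at least 2-fold. Groups did not overlap for 70.2% of genes, where chance gives 10%.

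Genes of the first set ran against the rescue set. Of 534 tested genes that were at least 2-fold higher in the first-set libraries labelled KO, 441 fell and 27 rose in rescue-set KO cells (median log2 fold change -1.75, camera adjusted p = 2.34e-56). Of 985 tested genes that were at least 2-fold lower there, 504 rose and 257 fell (median 0.70, camera adjusted p = 4.58e-06). Both calls were also made with an estimated correlation (adjusted p = 1.9e-06 and adjusted p = 0.000698). Of 4792 genes called in both sets, 1189 had the same sign (24.8%) and 3603 the opposite. Genes higher in the first set and lower in the rescue set numbered 1910, against 999 by chance, and genes lower and then higher numbered 1693, against 1020 by chance. Across 15490 genes, which are not independent replicates, the log2 fold changes of the sets had a Pearson correlation of -0.40 and a Spearman correlation of -0.34. A test of the difference between the sets' effects, with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, called 8521 of 17208 genes.

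Cells given back full-length ETO2 were compared with KO cells to ask which genes respond to its return. ENSG00000111058 rose from 0.0922 to 278 ± 21.6 CPM in FL (SD, n = 3; log2 fold change 11.54), and ENSG00000164266 rose from 0.0616 to 19.7 CPM. ENSG00000155974, which was higher in KO than in WT cells, fell from 14.6 to 0.0189 CPM (log2 fold change -8.96), and ENSG00000105205 fell from 19.8 to 0.022 CPM. The genes higher in the first-set libraries labelled KO rose as a list in FL, with 333 up and 73 down (median 1.03, camera adjusted p = 3.93e-15, and adjusted p = 4.76e-05 with an estimated correlation). The genes lower there were not called as a list by camera, with 345 up and 371 down (camera adjusted p = 0.918), but were by fry (fry adjusted p = 0.0163). The KO libraries enter this comparison and that of KO with WT, so part of the opposite movement may come from those shared libraries. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 10653 genes differed between FL and KO, with 5348 higher and 5305 lower, and 2542 and 1844 of them at least 2-fold.

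The deletion forms asked which domains of ETO2 the response needs. In D1, without the TAF110 domain, ENSG00000143851 rose from 4.71 ± 0.26 to 324 ± 7.45 CPM (SD, n = 3 each) and ENSG00000006747 fell from 78.4 to 1.56 CPM. In D2, without the HHR domain, ENSG00000140459 rose from 0.252 to 18.2 ± 3.7 CPM, and ENSG00000176566 had 0 counts against 55.8 CPM in KO. In D4, without the ZF domain, ENSG00000104112 rose from 0.251 to 22.9 ± 0.617 CPM and ENSG00000198756 fell from 67.2 to 0.0961 CPM. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 9369 genes differed from KO in D1 (4981 higher, 4388 lower), 11913 in D2 (5980 and 5933) and 9148 in D4 (4627 and 4521). Against FL, 10385 genes differed in D1 (5226 and 5159), 12089 in D2 (5746 and 6343) and 10819 in D4 (5191 and 5628).

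The genes higher in the first-set libraries labelled KO were read in each form, and the forms were not tested against one another. Against KO, 244 rose and 103 fell in D1 (median 0.46, camera adjusted p = 2.88e-05, and adjusted p = 0.000279 with an estimated correlation). In D2 263 rose and 121 fell (median 0.60, camera adjusted p = 8.85e-06, and adjusted p = 0.000202 with an estimated correlation). In D4 177 rose and 166 fell, and the list was not called by camera (median 0.04, camera adjusted p = 0.623), though it was by fry (fry adjusted p = 0.000669). Against FL the list was lower in D1 (median -0.48, camera adjusted p = 1.15e-08), in D2 (median -0.53, camera adjusted p = 5.34e-05) and in D4 (median -0.94, camera adjusted p = 4.37e-14), and each of these calls was also made with an estimated correlation. The genes lower in the first-set libraries labelled KO were called by camera in none of D1, D2 and D4 against KO (camera adjusted p = 0.216, 0.623 and 0.0885). By fry they were called in each (fry adjusted p = 1.81e-07, 0.000115 and 3.21e-06), with medians of 0.21, 0.11 and -0.34. The first-set score was 2.00 ± 0.011 in WT, -0.30 ± 0.022 in KO, 0.72 ± 0.028 in FL, -0.15 ± 0.021 in D1, 0.02 ± 0.036 in D2 and -0.17 ± 0.01 in D4 (SD, n = 3 each). Its difference from KO was 2.30 in WT, 1.02 in FL, 0.15 in D1, 0.32 in D2 and 0.13 in D4, each with an exact permutation p of 0.1, the smallest this design allows. With the 100 up and 100 down genes of smallest p the differences were 4.22 in WT, 1.84 in FL, 0.12 in D1 and 0.66 in D2. The small difference of D4 took the value -0.06 with the 100 up and 100 down genes of smallest p and -0.01 with a CPM filter. The level of ENSG00000129993 was lower in D1, D2 and D4 (579, 682 and 1020 CPM) than in FL (2210 CPM). Mitochondrial transcripts took 1.58% to 2.11% of counts in D1, D2 and D4 against 2.22% to 3.9% in WT, KO and FL. Gene length and log2 fold change against KO correlated across genes at -0.22 in D1, -0.32 in D2 and -0.18 in D4 (Spearman), and against FL at -0.17, -0.29 and -0.12. The loss of a domain was therefore not separated from these other differences between the forms and FL.

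**Figure D1:**
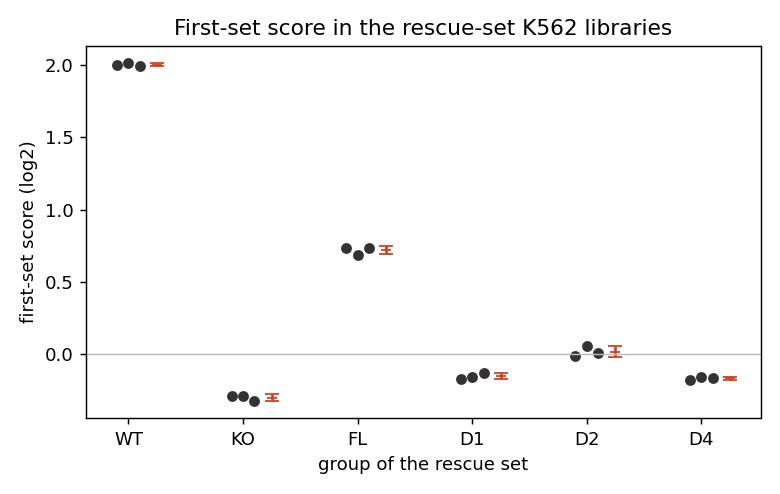
First-set score (mean log2 CPM of genes higher minus genes lower in the first-set libraries labelled KO) of each rescue-set library, with the mean and SD of each group of 3. WT lies near 2.00, FL near 0.72 and D1, D2 and D4 between -0.17 and 0.02.

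Total fetal liver compared KO with WT embryos in the organ where definitive red cells form. Transcripts of granulocytes were higher in KO livers. S100a9 (ENSMUSG00000056071, mm10 chromosome 3, 90692632 to 90695721), a calcium-binding protein of neutrophils, rose from 128 ± 36 to 2371 ± 1190 CPM (SD, n = 6 each; log2 fold change 4.21 ± 0.457 SE, adjusted p = 2.25e-05). KO 1 rose least, at 302 CPM, against 1760 to 3750 in the other KO livers and 87.3 to 176 in WT. Camp, an antimicrobial peptide of neutrophil granules, rose from 41.1 ± 26.3 to 745 ± 326 CPM, and Mpo, the peroxidase of early granules, rose from 282 ± 52.1 to 1172 ± 369 CPM. Of 24 granulocyte and monocyte genes 21 rose and 1 fell (adjusted over the list alone, 22 and 1), with a median log2 fold change of 2.37 (camera adjusted p = 1.23e-16, but adjusted p = 0.428 with an estimated correlation). All 10 tested mast cell, basophil and eosinophil genes rose, also adjusted over the list alone (median 2.99, camera adjusted p = 1.29e-13, but adjusted p = 0.242 with an estimated correlation, and 0.00324 without number 1 of both groups). Among them were Ms4a2, a chain of the IgE receptor, at 10.2 ± 2.84 against 1.72 ± 0.325 CPM, Epx, the eosinophil peroxidase (log2 fold change 3.45), and Mcpt8, a basophil protease. The genes with the largest rises included the mast cell and basophil protease gene Prss34, at 26.5 ± 14.5 against 0.92 ± 0.428 CPM, with BC100530 (4.78), Retnlg (4.30) and the cystatin-related genes Stfa2 and Stfa3 (4.18 each), whose family shares sequence.

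Megakaryocyte and platelet genes were also higher in KO livers, with 18 of 24 up and 2 down (adjusted over the list alone, 19 and 2; median 0.83, camera adjusted p = 2.69e-08, but adjusted p = 0.428 with an estimated correlation). Pf4, a platelet chemokine, rose from 102 ± 17.4 to 322 ± 69.3 CPM (SD, n = 6 each). Itga2b, an integrin chain of platelets, rose by 1.13 on the log2 scale and Gp1bb, part of the receptor for von Willebrand factor, by 1.55. Gata2, a transcription factor of progenitors and mast cells, rose from 9.86 ± 0.926 to 28.6 ± 6.73 CPM (adjusted p = 1.36e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of 82 ribosomal protein genes 71 rose and none fell (adjusted over the list alone, 73 and 0; median 0.64, camera adjusted p = 9.54e-18, but adjusted p = 0.429 with an estimated correlation). Rps21 rose from 352 ± 48 to 791 ± 106 CPM and Rpl38 from 99.8 ± 14.9 to 262 ± 59.9 CPM. Log2 fold changes in liver followed gene length across genes (Spearman -0.42), with a median of 0.52 in the shortest 10% of genes and -0.42 in the longest 10%, and with each library's length trend removed 46 ribosomal protein genes rose and 3 fell (median 0.35).

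Genes of red cell maturation were lower in KO livers. Alas2 (ENSMUSG00000025270, chromosome X, 150547375 to 150570638), the erythroid enzyme that starts heme synthesis, fell from 1480 ± 135 to 598 ± 148 CPM (SD, n = 6 each; log2 fold change -1.31 ± 0.15 SE, adjusted p = 2.3e-05). Ank1, a membrane anchor protein of red cells, fell by 1.35 on the log2 scale. Of 19 erythroid membrane and cytoskeleton genes 15 fell and none rose (adjusted over the list alone, 15 and 0; median -0.66, camera adjusted p = 6.35e-07, but adjusted p = 0.428 with an estimated correlation). Of 17 heme and iron genes 11 fell and none rose (adjusted over the list alone, 11 and 0; median -0.46, camera adjusted p = 0.00064, but adjusted p = 0.496 with an estimated correlation). Of 21 terminal erythroid genes 11 fell and 1 rose (adjusted over the list alone, 11 and 1; median -0.36, camera adjusted p = 0.00906, but adjusted p = 0.613 with an estimated correlation). Trim58, a ubiquitin ligase of late erythroblasts, fell by 1.54, and the riser was Alox15, a lipoxygenase also found in eosinophils, at 4.09 against 1.1 CPM. Kit, the stem cell factor receptor, fell from 68.6 ± 1.35 to 30.8 ± 7.77 CPM.

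Cell-cycle and endothelial genes were lower as well. Of 20 S phase genes 13 fell (adjusted over the list alone, 15; median -0.39, camera adjusted p = 0.00239, but adjusted p = 0.647 with an estimated correlation), Ccne2, a cyclin of S phase entry, by 1.18 and Pola1, a DNA polymerase subunit, by 1.10. Of 20 G2 and M phase genes 12 fell and 2 rose (adjusted over the list alone, 12 and 3; median -0.46, camera adjusted p = 0.00386, but adjusted p = 0.613 with an estimated correlation). Mki67, a marker of cycling cells, fell from 2338 ± 225 to 1454 ± 183 CPM (SD, n = 6 each). Of 20 endothelial and mesenchymal genes 11 fell and 1 rose (adjusted over the list alone, 11 and 1; median -0.68, camera adjusted p = 0.00091, but adjusted p = 0.613 with an estimated correlation), including Cdh5, an endothelial cadherin, which fell by 1.16. Of these 20 genes 7 fell with the length trend removed and 15 with the replicate block. Of 24 ETO2 partner and corepressor genes 13 fell and 4 rose (adjusted over the list alone, 14 and 4; median -0.35, camera adjusted p = 0.0408, but adjusted p = 0.647 with an estimated correlation). Rcor1, a corepressor, fell by 1.15 and Runx1t1, a relative of ETO2, by 1.20, while Irf2bp2, another corepressor, rose by 0.56. With the length trend removed 10 members of that list fell and 3 rose, and the list was no longer called (camera adjusted p = 0.143), nor was it with the replicate block (camera adjusted p = 0.0626).

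Among the globins of total liver, Hba-x (ENSMUSG00000055609, chromosome 11, 32276400 to 32278116), the embryonic zeta globin, rose from 52.6 ± 12.3 to 114 ± 31.5 CPM (SD, n = 6 each; log2 fold change 1.12 ± 0.185 SE, adjusted p = 0.000225). Hbb-y, an embryonic beta-type globin, had a log2 fold change of 0.26 (adjusted p = 0.352), which turned to -0.26 with the length trend removed, and Hbb-bh1 one of -0.32 (adjusted p = 0.212). Hbb-bh1 was called lower without number 1 of both groups (-0.54, adjusted p = 0.00339) and with the length trend removed (-0.81, adjusted p = 0.0125). The embryonic globin list was not called, with 1 of 3 up, also adjusted over the list alone (camera adjusted p = 0.424). Of 6 adult globins 2 rose and none fell, none adjusted over the list alone (median 0.30, camera adjusted p = 0.413): Hbb-bt and Hba-a2 each rose by 0.42, and their values turned to -0.04 and -0.06 with the length trend removed. The call of Hba-a2 was also lost with RLE factors (adjusted p = 0.0573), without the low-count filter (adjusted p = 0.113) and with embryo sex in the fit (adjusted p = 0.0685), and that of Hbb-bt without the filter (adjusted p = 0.0941). Hbb-bs was called lower with the length trend removed (-0.52, adjusted p = 0.0232), and without number 1 of both groups 4 of the 6 rose, among them Hba-a1 (0.60, adjusted p = 0.00768). Lin28a, an RNA-binding protein of fetal blood cells, rose from 4.33 ± 0.689 to 25 ± 8.77 CPM (adjusted p = 1.45e-05). Of 20 globin-switching regulators 10 fell and 2 rose, also adjusted over the list alone (camera adjusted p = 0.0832). Without number 1 of both groups 12 fell and 3 rose (camera adjusted p = 0.0171, but adjusted p = 0.303 with an estimated correlation), and with the length trend removed 7 fell and 6 rose (camera adjusted p = 0.73). Zbtb7a, a repressor of fetal globin, fell by 0.82 and Sox6, a repressor of embryonic globin, by 0.96.

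By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 7025 of 14128 genes differed in total liver, with 3434 higher and 3591 lower in KO, and 765 and 789 of them at least 2-fold. The groups did not overlap for 19.8% of genes, where chance gives 0.216%. Mitochondrial transcripts took 9.74% of counts in WT 1 and 14.3% in KO 1, against 1.12% to 1.39% in the other WT and 2.72% to 5.69% in the other KO livers. With the length trend removed 6165 genes were called, 4973 of them shared with those above.

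**Figure D2:**
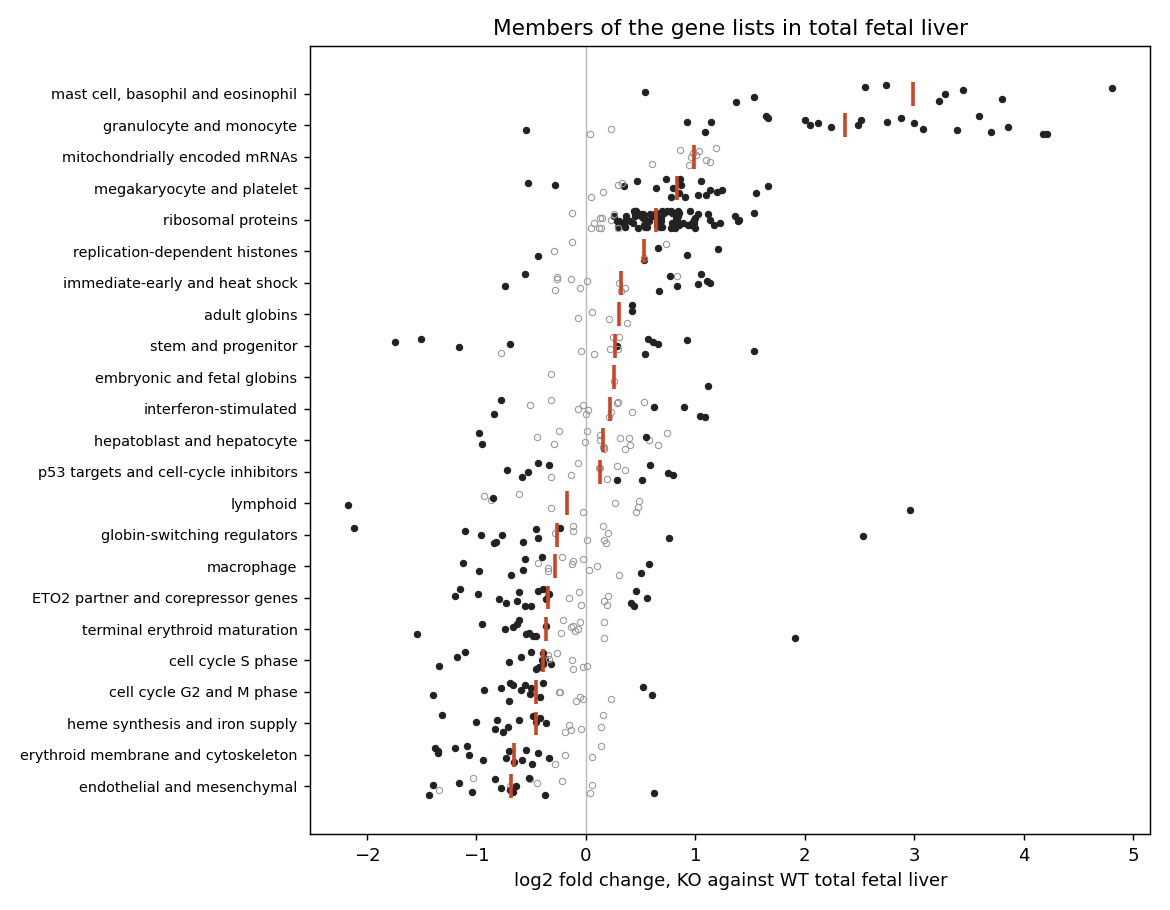
Log2 fold change (KO against WT) in total fetal liver of the members of each gene list, filled where the adjusted p was below 0.05, with the list median as a line. The median was 2.37 for granulocyte and monocyte genes and -0.66 for erythroid membrane genes.

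Cells sorted from fetal liver were compared by genotype within each gate, with 2 libraries per genotype. The labels do not say which markers the gates rest on. Xist stood at 246 to 949 CPM in WT 2 in the 7 gates and at 0 to 11.7 CPM in WT 1, KO 1 and KO 2, so sex was not balanced between genotypes, and it was not in the fit. In gate S0_med erythroid membrane genes and several other erythroid genes were lower in KO. Klf1, an erythroid transcription factor, fell from 203 ± 1.5 to 22.3 ± 7.46 CPM (SD, n = 2 each; log2 fold change -3.19, adjusted p = 0.00057), and Gata1, which drives erythroid genes, fell from 167 ± 11.2 to 39.4 ± 19.1 CPM (adjusted p = 0.03). Epor, the erythropoietin receptor, fell from 240 ± 165 to 15.1 ± 7.78 CPM, and the membrane channel gene Aqp1 from 363 ± 173 to 20.5 ± 6.16 CPM. Of 19 erythroid membrane genes 11 fell (adjusted over the list alone, 15), with a median of -2.94 (camera adjusted p = 8.18e-40, and adjusted p = 0.00564 with an estimated correlation). Of 17 heme and iron genes 2 fell (adjusted over the list alone, 14 fell and 1 rose; median -1.97, camera adjusted p = 1.48e-19, and adjusted p = 0.0107 with an estimated correlation). Of 21 terminal erythroid genes 4 fell (adjusted over the list alone, 10 fell and 1 rose; median -1.36, camera adjusted p = 1.9e-12, but adjusted p = 0.142 with an estimated correlation). Lists of other cell types moved in this gate too, though none of their genes was called. Granulocyte and monocyte genes were higher (24 of 24, none adjusted over the list alone; median 2.00, camera adjusted p = 2.76e-06, but adjusted p = 0.458 with an estimated correlation), as were mast cell, basophil and eosinophil genes (11 of 11, none adjusted over the list alone; median 3.12, camera adjusted p = 8.88e-06, but adjusted p = 0.183 with an estimated correlation). Stem and progenitor genes had a median of 1.66 (camera adjusted p = 0.00174, but adjusted p = 0.248 with an estimated correlation). Hepatocyte genes had a median of -2.43 (11 of 20 lower adjusted over the list alone; camera adjusted p = 3.75e-12, but adjusted p = 0.17 with an estimated correlation). A shift in the cells of the gate was therefore not separated from a change within cells. The only gene called higher was Tmx4, a thioredoxin-related membrane protein gene, at 328 ± 45 against 38.8 ± 46.6 CPM. Without KO S0_med 1 Klf1 (adjusted p = 0.15), Gata1 (adjusted p = 1), Epor (adjusted p = 0.0558) and Tmx4 (adjusted p = 0.137) were not called. Nor were Gata1 and Tmx4 without KO S0_med 2 (adjusted p = 0.0781 and 0.111) or WT S0_med 1 (adjusted p = 0.0588 and 0.273), and Aqp1 was called in each case.

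In S0_med 79 of 15346 genes differed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 78 of them lower. WT S0_med 1 held 120559 counts, of which 20.1% were mitochondrial. With the gate's own 4 libraries alone in the fit the count was 0. It was 50 without WT S0_med 1, 7 without KO S0_med 1, 61 without KO S0_med 2 and 1681 without WT S0_med 2. Without the 2 shallowest libraries of the sort 8 erythroid membrane genes fell (median -2.09), but adjusted p = 0.0775 with an estimated correlation, and the heme and iron list had a median of -1.47, but adjusted p = 0.119 with an estimated correlation.

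In gate S4-S5 all 4 tested embryonic globin genes rose in KO, also adjusted over the list alone (median 4.85, camera adjusted p = 5.23e-06, but adjusted p = 0.0942 with an estimated correlation). Hba-x stood at 4810 and 37600 CPM in the KO libraries against 643 and 850 in WT (log2 fold change 4.83, adjusted p = 0.00323 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and Hbb-y at 83290 ± 81500 against 2851 ± 1440 CPM (SD, n = 2 each). Without KO S4-S5 2 the change of Hba-x was 2.69 (adjusted p = 0.0564) and that of Hbb-y 3.17 (adjusted p = 0.245). Without WT S4-S5 1 neither was called (adjusted p = 0.0983 and 0.37), nor was Hbb-y without WT S4-S5 2 (adjusted p = 0.0681). Hbb-bs, an adult beta globin, stood at 322400 ± 134000 against 131100 ± 62500 CPM and was not called (adjusted p = 0.339). Of 20 S phase genes 9 fell (adjusted over the list alone, 16; median -1.73, camera adjusted p = 5.47e-17, but adjusted p = 0.0533 with an estimated correlation). Pcna, the sliding clamp of DNA replication, fell from 483 ± 22.6 to 93.4 ± 37.4 CPM, and was not called without KO S4-S5 2 (adjusted p = 0.215) or WT S4-S5 1 (adjusted p = 0.172). Of 20 G2 and M phase genes 4 fell (adjusted over the list alone, 15; median -1.44, camera adjusted p = 1.05e-13, but adjusted p = 0.0942 with an estimated correlation). Of 17 heme and iron genes 3 fell (adjusted over the list alone, 8; median -1.14, camera adjusted p = 1.22e-05, but adjusted p = 0.201 with an estimated correlation).

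Megakaryocyte and myeloid transcripts were higher in the same gate. Of 24 megakaryocyte genes 3 rose (adjusted over the list alone, 10; median 2.97, camera adjusted p = 5.05e-07, but adjusted p = 0.201 with an estimated correlation), among them Pf4, at 165 and 1600 CPM in KO against 53.6 and 130 in WT, and Vwf, the von Willebrand factor gene (3.05). Without KO S4-S5 2 the log2 fold change was 0.85 for Pf4 (adjusted p = 0.788) and 1.32 for Vwf (adjusted p = 0.577), and without WT S4-S5 1 it was 2.76 (adjusted p = 0.404) and 2.55 (adjusted p = 0.333). Of 24 granulocyte and monocyte genes 1 rose (adjusted over the list alone, 7; camera adjusted p = 7.03e-11, but adjusted p = 0.221 with an estimated correlation), namely Csf1r, a receptor of monocytes and macrophages, which was not called without KO S4-S5 2 (adjusted p = 0.29), WT S4-S5 1 (adjusted p = 0.417) or WT S4-S5 2 (adjusted p = 0.0522). Macrophage genes of S4-S5 had a median of 2.26 (17 of 19 higher, camera adjusted p = 0.000118, but adjusted p = 0.317 with an estimated correlation). Stem and progenitor genes had a median of 2.77 (16 of 18 higher, camera adjusted p = 0.000118, but adjusted p = 0.201 with an estimated correlation). A shift in the cells of S4-S5 was not separated from a change within cells, for these lists or for its globin and cell-cycle genes. In S4-S5 435 genes differed by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with 277 higher and 158 lower in KO. With the gate's own 4 libraries alone in the fit the count was 0. It was 58 without KO S4-S5 2, 7 without WT S4-S5 1, 762 without KO S4-S5 1 and 1028 without WT S4-S5 2.

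In the other gates few or no genes passed the test. In S3-C Hba-x rose from 248 ± 46.9 to 5068 ± 441 CPM (SD, n = 2 each; log2 fold change 4.36, adjusted p = 0.0451 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and no gene was called there when any 1 of the 4 libraries was left out. Hba-x was also not called there with the replicate block (adjusted p = 0.0698), with RLE factors (adjusted p = 0.109), with the gate's own libraries alone (adjusted p = 0.137), with the length trend removed (adjusted p = 0.168), or by limma or without the 2 shallowest libraries (adjusted p = 1 each). The embryonic globin list of S3-C had a median of 4.45 over 4 genes, with 1 up (adjusted over the list alone, 3; camera adjusted p = 2.59e-13, and adjusted p = 0.0124 with an estimated correlation, but 0.0857 without the 2 shallowest libraries of the sort). Other lists of S3-C moved as well, with no gene called over the list alone: macrophage genes (17 of 19 higher, median 1.27, camera adjusted p = 6.22e-08, but adjusted p = 0.399 with an estimated correlation), megakaryocyte genes (median 1.27, camera adjusted p = 3.07e-05, but adjusted p = 0.428 with an estimated correlation) and S phase genes (20 of 20 lower, median -0.81, camera adjusted p = 4.09e-11, but adjusted p = 0.177 with an estimated correlation). A shift in the cells of the gate was not separated from a change within cells. In S1 the mast cell, basophil and eosinophil list had a median of 7.39 (none of 11 called, 10 up adjusted over the list alone; camera adjusted p = 1.98e-29, and adjusted p = 0.00324 with an estimated correlation). Prg2, a granule protein of eosinophils, stood there at 667 ± 17.6 against 0.41 ± 0.21 CPM. The granulocyte and monocyte list of S1 had a median of 4.18 (5 of 24 up adjusted over the list alone; camera adjusted p = 1.26e-34, and adjusted p = 0.0325 with an estimated correlation, but 0.064 without the 2 shallowest libraries), and its embryonic globins a median of 3.52 (4 of 4 up adjusted over the list alone; camera adjusted p = 7.5e-11, and adjusted p = 0.0197 with an estimated correlation). The adult globins of S1 were higher as well (6 of 6, 3 adjusted over the list alone; median 2.27, camera adjusted p = 7.32e-08, but adjusted p = 0.0648 with an estimated correlation, and 0.0362 with the replicate block). Macrophage genes of S1 had a median of 2.01 (18 of 19 higher, camera adjusted p = 1.34e-12, but adjusted p = 0.0778 with an estimated correlation). Hepatocyte genes of S1 had a median of -1.29 (camera adjusted p = 5.86e-09, but adjusted p = 0.214 with an estimated correlation). In S2 the embryonic globins had a median of 1.94 (2 of 4 up adjusted over the list alone; camera adjusted p = 1.78e-05, but adjusted p = 0.21 with an estimated correlation), and none was up over the list alone without the 2 shallowest libraries (median 1.63) or with the length trend removed (median 2.07). Other lists of S2 moved too, namely granulocyte and monocyte genes (24 of 24 higher, median 3.12, camera adjusted p = 1.34e-14), mast cell, basophil and eosinophil genes (median 3.17, camera adjusted p = 1.08e-06), megakaryocyte genes (median 1.17, camera adjusted p = 1.94e-06) and hepatocyte genes (median -1.31, camera adjusted p = 2.14e-10), but each had adjusted p = 0.21 with an estimated correlation. Macrophage genes of S2 had a median of 0.84 (camera adjusted p = 2.58e-05, but adjusted p = 0.343 with an estimated correlation). In S3-m the embryonic globin list was not called (median 1.5, camera adjusted p = 0.0775). Granulocyte and monocyte genes had a median of 3.81 there (camera adjusted p = 3.61e-15). Mast cell, basophil and eosinophil genes had one of 3.86 (camera adjusted p = 4.22e-05), and hepatocyte genes one of -2.15 (camera adjusted p = 7.68e-17). With an estimated correlation these moved lists had adjusted p = 0.475, 0.475 and 0.348. In S0_low 12 of 20 hepatocyte genes were lower adjusted over the list alone (median -2.50, camera adjusted p = 4.56e-25, but adjusted p = 0.091 with an estimated correlation). Without the 2 shallowest libraries, of which KO S0_low 1 is 1, none was lower over the list alone (median -2.25, camera adjusted p = 1.53e-11, but adjusted p = 0.401 with an estimated correlation). Other lists of S0_low moved too: granulocyte and monocyte genes (median 1.62, camera adjusted p = 0.00075, but adjusted p = 0.419 with an estimated correlation), adult globins (median 1.63, camera adjusted p = 5.17e-05, but adjusted p = 0.316 with an estimated correlation), endothelial genes (median -1.52, camera adjusted p = 1.7e-06, but adjusted p = 0.316 with an estimated correlation) and erythroid membrane genes (median -1.05, camera adjusted p = 8.74e-05, but adjusted p = 0.336 with an estimated correlation). The S0_low values rest in part on KO S0_low 1, which held 9918 counts. In that library Hbb-bs stood at 2910 CPM from 85 counts, against 662 CPM in KO S0_low 2 and 631 and 368 in WT. In S1, S2, S3-m and S0_low too, a shift in the cells of the gate was not separated from a change within cells.

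edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 0 genes in S0_low (545 at an unadjusted p under 0.05, 30 by DESeq2, 35 by limma), 0 in S1 (671, 85 and 10), 0 in S2 (469, 41 and 1) and 0 in S3-m (1299, 126 and 2). It called 1 gene in S3-C, against 28 by DESeq2 and 0 by limma. The test of the genotype by gate interaction called 4 genes (635 at an unadjusted p under 0.05, 66 by DESeq2 and 0 by limma): Atp1b2, a sodium pump subunit (adjusted p = 0.0111), Aqp1 and Abcg4, a lipid transporter gene (adjusted p = 0.0234 each), and Gm32051 (adjusted p = 0.0485). The log2 fold change of Aqp1 was -4.12 in S0_med and -2.87 in S4-S5, and -0.34 in both S1 and S2. Hba-x did not pass the interaction test (adjusted p = 0.0603).

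**Figure D3:**
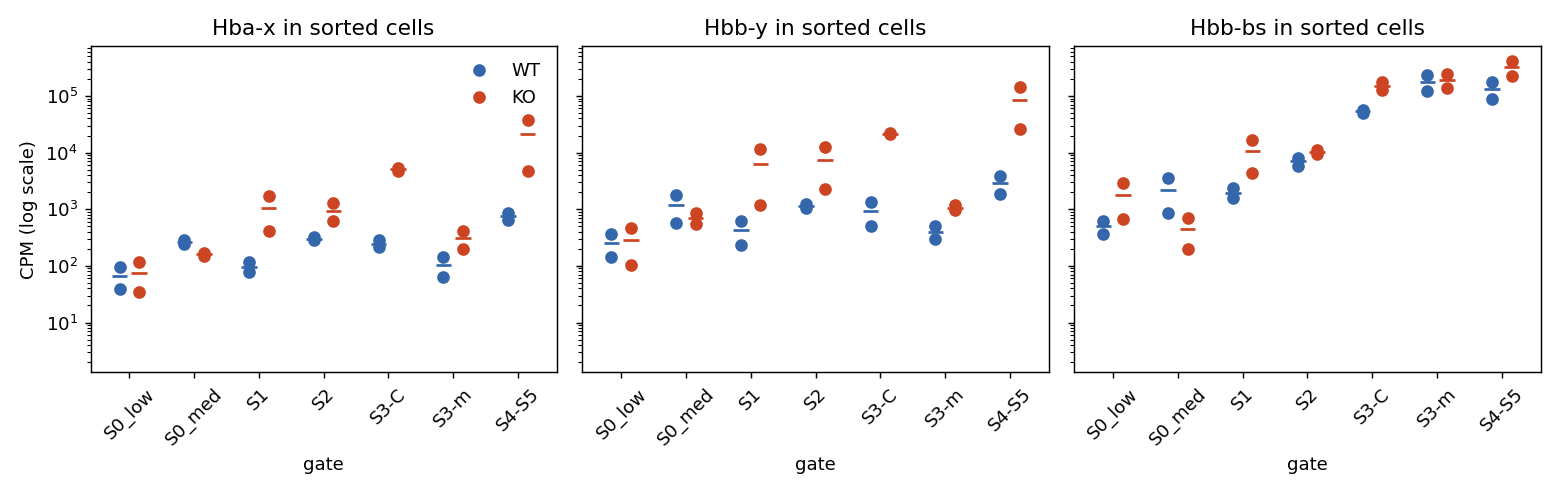
CPM (log axis) of Hba-x, Hbb-y and Hbb-bs in each sorted library by gate and genotype, with a horizontal bar at each mean of 2. In S3-C the mean of Hba-x was 5068 CPM in KO and 248 in WT.

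**Figure D4:**
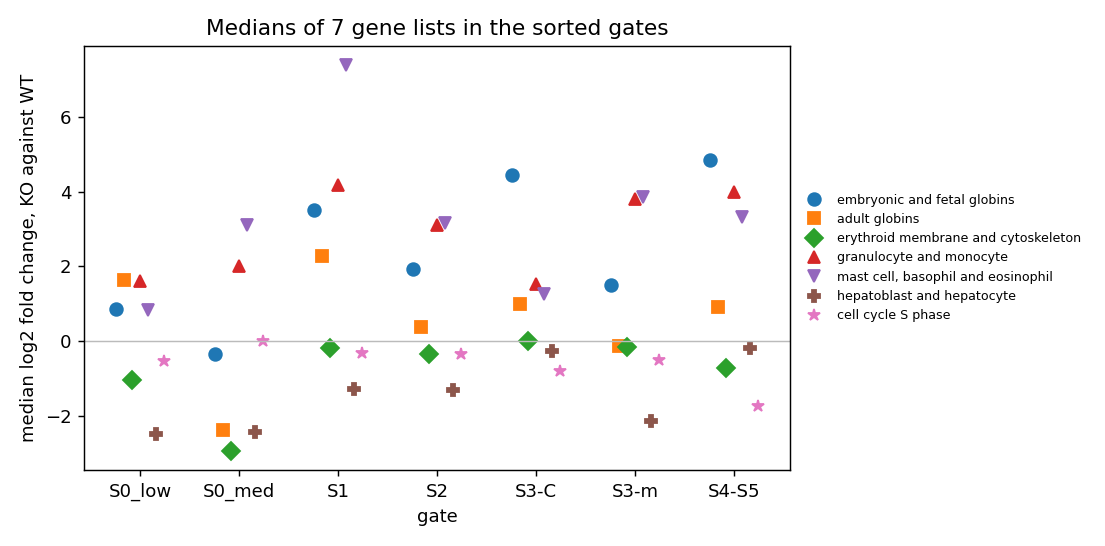
Median log2 fold change (KO against WT) of 7 gene lists in each of the 7 gates. The erythroid membrane list reached -2.94 in S0_med and the embryonic globins 4.85 in S4-S5.

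Calls in the sort were compared with those in total liver over 13547 genes tested in both. Of the genes lower in S0_med 43 were also lower in KO liver, against 19.7 by chance (Fisher's exact test, adjusted p = 4.93e-08). Of the genes higher in S4-S5 136 were higher in KO liver, against 68 by chance (Fisher's exact test, adjusted p = 2.28e-18), and 81 were lower in both, against 40.4 by chance (Fisher's exact test, adjusted p = 1.86e-11). Among changes of at least 2-fold, 63 were higher in both, against 14.6 by chance (Fisher's exact test, adjusted p = 9.44e-23), but 12 were lower in both, against 8.23 by chance (Fisher's exact test, adjusted p = 0.541). The sign was shared by 91.5% of the genes called in both liver and S0_med and by 81% of those called in both liver and S4-S5.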

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

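The tests of exchanged labels in the first K562 set, of a lower share of erythroid cells, of globin RNA of every kind and of primitive erythroid cells were chosen only after the results were seen.

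The effect of KO differed between the K562 sets for 8521 genes, by a test of the difference itself. The Pearson correlation of their log2 fold changes across genes was -0.40. Group labels of the first set exchanged would give such a value, but it only restates the opposite effects. Different clones or different ways in which ETO2 was lost do not by themselves predict a reversal, but neither was tested. The correlation alone therefore does not settle which labels are right. The names of the first set's deposited files carry the opposite words to its labels. ENSG00000129993, which stood above WT in all groups given back ETO2, also reversed. It was higher in first-set libraries labelled KO (158 CPM) than Control (75.8 CPM), but lower in rescue-set KO (79.1 CPM) than WT (170 CPM). The file names and this identifier go with exchanged labels, though the identifier's name was not established here. First-set directions are therefore not read as effects of the loss of ETO2. No biological explanation was tested.

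In total liver several libraries lay far from the others of their group, in 32 of 160 values examined, where chance gives about 1 in 20. WT 1 stood apart with a mitochondrial share of 9.74% and 22.9% of counts in its 10 most abundant genes. It was high in mt-Nd1, a mitochondrial subunit (18600 CPM), in the adult globins Hbb-bs (33900) and Hba-a2 (7650), in the neutrophil gene Camp (92.1), in Cdh5 of endothelium (91.4), in the macrophage genes Clec4f (24.7), Axl (82.6), Timd4 (27.7) and Spic (14.5), and in the immediate-early gene Jund (43.4). It was low in the regulators Zbtb7a (133), Nr2c2 (12), Rcor1 (57.8) and Ncor1 (93.7), in the replication gene Pola1 (58.5) and in Sik2 (9.81). KO 1 stood apart with a mitochondrial share of 14.3%, 21.7% of counts in its 10 most abundant genes and 28100 CPM of mt-Nd1. KO 1 was also high in Runx1t1 (25.9), Kit (45.8), Clec4f (6.18), Axl (53.8) and Timd4 (18.3), and low in Irf2bp2 (63.2). WT 2 was high in Irf2bp2 (59.6), KO 4 in Cbfa2t3 (36.1) and Jund (83.5), and KO 5 had a globin share of 4.67%. Without number 1 of both groups 9653 genes were called in liver, of which 6967 were among the 7025 called with all libraries.

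The rise of myeloid and ribosomal protein genes and the fall of erythroid genes in KO livers was weighed against technical explanations. With each library's length trend removed, the granulocyte and monocyte list still had a median of 2.03, after 2.37, and 21 members rose before and after, which argues against gene length as its whole cause. The same holds for erythroid membrane genes, with a median of -0.54 after -0.66 and 13 members lower after 15. For ribosomal protein genes the median went to 0.35 from 0.64 and the risers to 46 from 71, and their short length keeps a length bias and a biological change from being told apart. A lower erythroid share alone would raise other cell types alike, but granulocyte and monocyte genes moved above endothelial and mesenchymal genes by 2.87 ± 0.46 (SE). The endothelial list was chosen with its values known and had the lowest median of these cell types (-0.68), so other lists would leave a narrower gap. The mast cell, megakaryocyte, hepatocyte and macrophage lists had medians of 2.99, 0.83, 0.16 and -0.28. A change in the number of myeloid cells or in their transcripts stays open, as a hypothesis from the same data.

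The embryonic globin transcripts Hba-x and Hbb-y lay above WT in both KO libraries of 5 gates of the sort. Same-numbered gates may come from the same sample, so these gates do not count as separate repeats. With 2 libraries per genotype, chance leaves 33.3% of genes without overlap, and 26.3% (S3-m) to 42.2% (S0_med) had none. Hba-x was called in S3-C and S4-S5 only. In S0_med Hba-x went the other way, at 149 and 171 CPM in KO against 239 and 287 in WT. If more globin RNA of every kind were the cause, the ratio of Hbb-y to Hbb-bs should not differ, and it was higher in both KO libraries in 4 of the 7 gates. The adult Hbb-bs itself was higher in both KO libraries in 5 gates. In S1, S2, S3-C and S4-S5 Hba-x and Hbb-y were higher as well, which goes with that explanation. In S3-m Hba-x and Hbb-y were higher but Hbb-bs was not, and in S0_low Hbb-bs was higher but they were not, which goes against it. Hbb-bs of S0_low rested on 85 counts in KO 1 and on 662 CPM in KO 2 against 631 and 368 in WT. In S3-C there were 16.9 and 12.3 Hbb-y counts per 100 of Hbb-bs in KO against 0.891 and 2.66 in WT, but 2 libraries per group do not settle this. If primitive erythroid cells lay in the KO gates, Hbb-bh1 should be higher too, and it was in 4 of those 5 gates. Such cells may therefore contribute, and they cannot be told apart from embryonic globin expression in definitive cells, since total counts do not show which cells held the transcripts.

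The interaction test called 4 genes: Atp1b2 (adjusted p = 0.0111), Aqp1 (adjusted p = 0.0234), Abcg4 (adjusted p = 0.0234) and Gm32051 (adjusted p = 0.0485), by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The edgeR fit treated all libraries of the sort as independent, though same-numbered gates may come from the same sample. limma with duplicateCorrelation, which let libraries of the same genotype and number correlate, called none. Its consensus correlation was only 0.03, and edgeR with the replicate block called more genes than without it. The loss under limma was therefore not traced to libraries from the same sample. Atp1b2 had a log2 fold change of -3.67 in S0_med and 0.97 in S3-m, and Abcg4 had -4.93 in S0_med and -2.90 in S4-S5. Gm32051 had -1.82 in S0_med and 3.36 in S4-S5.

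Other splits of the same libraries were tested in the same way. In total liver 1 of 100 splits drawn from 462, the real one, gave at least 7025 genes. The highest other split, which exchanged KO 1 and WT 2, gave 4388. A share of 1 in 100 is the smallest these draws allow, and it holds only if the livers are independent, which the labels do not say. In K562 cells the 10 splits of 3 against 3 are too few to reach such a share. In the first set the real split gave 7916 and the highest other 0. In the rescue set the real splits gave 8767 (KO and WT), 10653 (FL and KO), 9369 (D1 and KO), 9148 (D4 and KO), 10385 (D1 and FL), 12089 (D2 and FL) and 10819 (D4 and FL), each with 0 in the highest other by edgeR, and 11913 (D2 and KO) with 1 in the highest other.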

How the results depend on the processing

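Alternatives chosen only after the data were seen were the sort without its 2 shallowest libraries, the rescue set without D1 3, D2 2 and D4 2, liver without number 1 of both groups, removal of the length trend, and a block for the first-set lists. The counts of called genes in K562 cells and in total liver stayed within 1.5 times their values under each alternative tried. In liver they ran from 6158 without KO 4 to 9653 without number 1 of both groups, with 6165 when the length trend was removed. Of the liver gene values under alternatives 1557 of 1596 kept their direction and side of the threshold, and of those in the sort 744 of 910. Library sizes without globins were not run for K562 cells, whose globins could not be named. The cause was not tested for any moved value below unless it is given.

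Without D1 3, D2 2 and D4 2, which stood apart from their groups, the rescue set gave 11517 genes (KO and WT), 12695 (FL and KO), 10904 (D1 and KO), 11958 (D2 and KO), 10511 (D4 and KO), 11841 (D1 and FL), 12401 (D2 and FL) and 12151 (D4 and FL).

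In the sort the counts were small and moved. RLE factors gave 126 genes in S0_med, 0 in S3-C and 13 for the interaction. No filter gave 41 in S0_low, 253 in S0_med, 231 in S1, 86 in S2, 12 in S3-C, 226 in S3-m, 865 in S4-S5 and 262 for the interaction. DESeq2 gave 30 in S0_low, 302 in S0_med, 85 in S1, 41 in S2, 28 in S3-C, 126 in S3-m, 1105 in S4-S5 and 66 for the interaction. limma gave 35 in S0_low, 159 in S0_med, 10 in S1, 1 in S2, 0 in S3-C, 2 in S3-m, 802 in S4-S5 and 0 for the interaction. Fits of each gate alone, with fewer samples, gave 24 in S0_low, 0 in S0_med, 84 in S1, 1 in S2, 0 in S3-C and 0 in S4-S5. Without the 2 shallowest libraries S1 gave 1, S3-C 0 and S4-S5 819. The length trend removed gave 0 in S3-C. The replicate block gave 2 in S0_low, 0 in S3-C, 100 in S0_med, 479 in S4-S5 and 6 for the interaction. The median log2 fold change of all genes in S0_med shifted by -0.11 with RLE factors and by -0.20 with DESeq2, and in S4-S5 by 0.11 with globins left out of library sizes.

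With the replicate block the first K562 set gave 7552 genes and liver 7778. In the rescue set the block gave 8767 (KO and WT), 10693 (FL and KO), 9405 (D1 and KO), 11854 (D2 and KO), 9178 (D4 and KO), 10383 (D1 and FL), 12052 (D2 and FL) and 10820 (D4 and FL). With the block camera called the first-set lists of higher and lower genes in 7 and 1 of 8 comparisons. Of the gene lists in liver 11 were called, and 11 with the block, where ETO2 partners and corepressors lost their call (camera adjusted p = 0.0626) and mitochondrially encoded mRNAs gained one (camera adjusted p = 2.2e-06). The number was 14 without number 1 of both groups, 10 with the length trend removed and 0 with an estimated correlation, which called 1, the mast cell, basophil and eosinophil list, without number 1 of both groups. With the length trend removed Hbb-bt went to -0.04 (adjusted p = 0.857 by edgeR) and Hba-a2 to -0.06 (adjusted p = 0.777).

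The first-set score minus that of KO became 2.52 for WT, 1.10 for FL and 0.11 for D4 with a prior count of 0.5. With 100 up and 100 down genes it became 4.22 for WT, 1.84 for FL, 0.12 for D1, 0.66 for D2 and -0.06 for D4, and with a CPM filter 2.44, 1.18, 0.10, 0.36 and -0.01.

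With each library left out in turn, a lone sample in a group was assumed to vary like the other groups. The counts ran from 6710 to 7594 in the first set, from 7779 to 8003 for KO and WT, from 9768 to 10086 for FL and KO, from 8053 to 8939 for D1 and KO, from 10992 to 12151 for D2 and KO and from 7705 to 8747 for D4 and KO. Against FL they ran from 9530 to 9918 (D1), from 11469 to 12314 (D2) and from 10129 to 10381 (D4). In liver they ran from 6158 without KO 4 to 8695 without WT 1. In the sort they ran from 0 to 10 in S0_low (without KO 2), from 7 (without KO 1) to 1681 (without WT 2) in S0_med, from 0 to 2 in S1 (without KO 2), from 0 to 39 in S3-m (without KO 2, and 13 without WT 2) and from 7 (without WT 1) to 1028 (without WT 2) in S4-S5, and were 0 in S2 and S3-C. The score differences ran from 2.29 to 2.31 (WT), 1.01 to 1.04 (FL), 0.14 to 0.16 (D1), 0.30 to 0.33 (D2) and 0.12 to 0.14 (D4). In the sort most 4-fold simulated changes were missed in S0_med and S4-S5, and the part that depth plays in this was not separated from the spread between libraries.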

Other observations

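The tests without number 1 of both liver groups and with the length trend removed were chosen only after the results were seen. In total liver the other gene lists were not called by camera. Of 18 stem and progenitor genes 7 rose and 4 fell, also adjusted over the list alone (median 0.27, camera adjusted p = 0.345), and Cd34, a surface protein of progenitors, rose by 0.61 while Kit fell by 1.16. Of 18 macrophage genes 6 fell and 2 rose, also adjusted over the list alone (median -0.28, camera adjusted p = 0.196), with Timd4, a receptor for dying cells, lower by a log2 fold change of -0.98. Of 12 lymphoid genes 1 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.919), namely Nkg7 of cytotoxic cells (2.96), Rag1 of lymphocyte precursors (-2.17) and Pax5 of B cells (-0.85), which was no longer called with the length trend removed (-0.54, adjusted p = 0.108). Of 20 hepatocyte genes 1 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.733), and Apob, a lipoprotein of hepatocytes, fell from 1526 ± 58.2 to 772 ± 128 CPM (SD, n = 6 each). Without number 1 of both groups 15 of these hepatocyte genes rose and 3 fell (camera adjusted p = 0.000744, but adjusted p = 0.422 with an estimated correlation).

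Stress and cycle-arrest genes of liver moved both ways. Of 18 p53 targets and cell-cycle inhibitors 5 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.733), with Gadd45a, a DNA damage gene, up by 0.75 and Sesn2, a stress sensor, at -0.72. Of 18 interferon-stimulated genes 4 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.687), and Bst2, an antiviral membrane protein, rose by 1.09. Of 19 immediate-early and heat shock genes 7 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.155), among them Zfp36, which speeds mRNA decay (1.13). Of 9 replication-dependent histone genes 4 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.163). None of 10 mitochondrially encoded mRNAs passed in edgeR (median 0.99, camera adjusted p = 0.157), but all 10 rose with the replicate block (median 1.44, camera adjusted p = 2.2e-06, but adjusted p = 0.35 with an estimated correlation) and without number 1 of both groups (median 1.69, camera adjusted p = 4.7e-05, but adjusted p = 0.351 with an estimated correlation). In S4-S5 none of 5 sex-linked genes passed in edgeR (camera adjusted p = 0.796).

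In S4-S5 Ctss, a protease of macrophages, rose from 2.19 to 87 CPM (log2 fold change 5.30, adjusted p = 0.00755 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of 20 interferon-stimulated genes 2 rose there (adjusted over the list alone, 7; median 3.41, camera adjusted p = 0.000179, but adjusted p = 0.214 with an estimated correlation). Of 20 immediate-early genes 3 rose (adjusted over the list alone, 6; camera adjusted p = 8.91e-05, but adjusted p = 0.0533 with an estimated correlation), among them Junb, at 237 against 19.6 CPM. Junb was not called without KO S4-S5 2 (adjusted p = 0.18), and neither Junb (adjusted p = 0.19) nor Ctss (adjusted p = 0.147) without WT S4-S5 1. Without WT S4-S5 1 the count of called genes in this gate was 7.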
